A study of Mus musculus with 4 samples.

How the data were processed

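ATAC-seq peak lists of 4 libraries of the mouse neuroblastoma line 9464D were used, 2 from cells electroporated with Cas9 complexes against H2afy and 2 from control cells, grouped by the sample titles. Per the labels' protocols, each reaction used 50000 cells and the transposed DNA was amplified by PCR and size-selected with beads. The submitters' processing notes name Bowtie2, SAMtools, Picard, deepTools, MACS2 and bedtools and the build mm10, with no versions, roles or parameters. The read filters, the offset for the transposase and the settings of the peak caller are not given in the sources used here. One list per library was deposited, so peaks were called per library and not on pooled reads. A call depends on the depth of its library, so that a region missing from a list may be open below the threshold.

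Each deposited list is in narrowPeak layout. The score deposited for each peak is 10 times its −log10 q, as whole numbers, and was not used. The fold enrichment the authors deposited is the ratio of the pileup at the summit to the local background of the same library, with 1 added to both, as judged from the values. The authors also deposited −log10 of the p value and of the q value at the summit. The smallest −log10 q was 2.03 to 2.06 in the 4 lists, so the lists end near the same threshold. Fold and −log10 values served only to rank or filter peaks within a library, apart from the recovery of reads described last.

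Peaks on the standard chromosomes were kept, which left out 20 to 22 peaks per library on scaffolds. No peak ended beyond a GRCm38 chromosome. Gene models were from GENCODE M21 protein-coding transcripts, and sequence from GRCm38.p6, the assembly of mm10. Peaks of the 4 libraries were merged where they overlapped by at least 1 bp, and a library called a region if any of its peaks overlapped it. A region called in both libraries of a group and neither of the other was exclusive to that group. The same was done for the 2 other ways to split the libraries into pairs. A promoter region overlapped the 1 kb on either side of a protein-coding transcription start, and every other region was distal. Regions went to the protein-coding gene with the nearest start within 50 kb for the gene lists. Agreement was the Jaccard index from bedtools.

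Promoter share, chromosomes, gene lists and motifs were compared between KO-only and control-only regions with two-sided Fisher's exact tests, adjusted by the Benjamini-Hochberg procedure over 20 chromosomes, 20 lists or 25 motifs at a threshold of 0.05. Intervals of log2 odds ratios are at 95% by Woolf's method with 0.5 added to each cell. These tests count regions, which are not biological replicates, and the intervals cover counting error only. Motifs were consensus sequences searched on both strands within 100 bp of the summit of the strongest peak. The lists held 447 genes found in the annotation, and 1 named gene was not found. They covered adrenergic and mesenchymal transcription factors, catecholamine and neuron genes, matrix genes, MHC class I, interferon, chemokine and NF-kB, checkpoint, H2A variant, Polycomb and DNA methylation, Hox, neural crest, cell cycle, axon guidance, WNT, BMP and TGF-beta and housekeeping genes. Another 4 lists held markers of macrophages, lymphocytes, endothelium and epithelium.

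The named genes were chosen by rule: H2afy, up to 4 members of each list with an exclusive region, the 10 genes with the most KO-only regions net of control-only ones and the 10 of the reverse, the 5 regions of each kind with the highest weakest −log10 q, and the 10 promoter regions of each kind by the same measure. Where a list had more members with exclusive regions, the others are named to complete its count, a choice made after their values were seen. The members named for called promoters were chosen likewise. Some genes and motifs that the rule or the lists include are not reported here.

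Read totals were not used here. A fold and a Poisson p that are both computed from a whole number of reads at the summit fix that number, so the pair of reads and background that gives both deposited values was searched for each peak. Within 1e-04 on the −log10 scale a whole number was found for at least 99.997% of the peaks of each library. The median peak had 21 reads at its summit in each library, and the background differed between libraries as the results give. For 26742 of the regions called in all 4 libraries, log2(reads + 0.5), centred on the median of each library, was tested with limma using a variance trend and robust moderation. Each library has its own summit within a region, so the compared positions can differ. This test, the medians per chromosome and in bins of 10 Mb (at least 20 regions each, bootstrap of 2000 draws) and the search of 6-base words were chosen after seeing the data. The bootstrap drew regions and not libraries, so its intervals do not cover the spread between libraries or cultures.

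Steps were tested on simulated data. The recovery gave the true read number for 99.99% of 20000 simulated peaks. All 200 planted KO-only and 200 planted control-only regions among 20000 were found. A motif with a log2 odds ratio of −0.6 was called in 97.0% of 100 simulations over 3684 regions and 0.417% of unchanged motifs were called. With limma over 26742 regions, 53.0% of regions changed by 1 on the log2 scale and 82.0% of those changed by 1.5 were called, and 0 of the 135 calls were unchanged regions. This simulation used a dispersion of 0.001, the lower bound set for the estimate from the replicates and close to counting noise alone, so it does not cover a larger spread between cultures.

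Alternatives were peaks with a −log10 q of 5 or more, the 20000 strongest peaks per library, summit windows, a minimum cover of 0.25 of the region, strong exclusive regions, a start window of 2.5 kb, gene distances of 10 and 200 kb, strata of chromosome or of 5 classes of GC content, a motif window of 50 bp on each side, a replicate block, other rank values and each library left out in turn. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0, matplotlib 3.10.9, bedtools 2.31.1, samtools 1.23.1, R 4.3.3 and limma 3.58.1 were used.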

Results

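Chromatin accessibility was measured by ATAC-seq in 9464D cells, a mouse neuroblastoma line derived from a tumour of a mouse that carries a MYCN transgene. In ATAC-seq a transposase inserts sequencing adapters into open chromatin, and places where the resulting fragments pile up are called as peaks. The cells had received Cas9 complexes against H2afy (2 libraries, called KO here) or were controls (2 libraries). H2afy encodes the histone variant macroH2A1, which replaces ordinary H2A in part of the nucleosomes. The deposited design names the question: whether this histone holds the epigenetic state of neuroblastoma cells in place. Each reaction used 50000 cells. The labels number the replicates and do not say whether they were separate cultures, so the spread between them may be technical.

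The peak lists of the KO and control libraries were alike in size. On the standard chromosomes KO replicates 1 and 2 held 40321 and 39019 peaks, and control replicates 1 and 2 held 39802 and 41128. The group means were 39670 ± 921 (SD, n = 2) and 40465 ± 938 (SD, n = 2), a difference smaller than either SD. Peaks covered 20.9 and 20.0 Mb in the KO libraries and 20.4 and 20.9 Mb in the control libraries, and their median width lay between 430 and 439 bp. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so no p is given for values per library. The depth differed more than the peak number. The background pileup that the authors' fold and p values imply was 0.806 and 0.791 reads in the KO libraries and 0.858 and 0.967 in the control libraries, so that the deepest library, control replicate 2, had 1.22 times the background of KO replicate 2. Peak lists of replicates overlapped slightly more than lists of different groups. The Jaccard index, the shared length over the joint length, was 0.660 for the KO pair and 0.661 for the control pair, and 0.628 to 0.633 for the 4 pairs of a KO with a control library.

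The H2afy locus stayed open in both groups. Its promoter region (mm10 chromosome 13, 56134804 to 56135827, minus strand) carried a peak in all 4 libraries, with a fold over background of 7.64 and 9.52 in the KO and 10.2 and 7.99 in the control libraries. These folds, like all others per peak below, are the authors' own values and describe a peak within its list. Small insertions or deletions made by Cas9 leave a promoter in place, so this peak does not check the labels. An intronic region of H2afy (chromosome 13, 56113096 to 56113331) was called in both KO libraries and in neither control library, at folds of 4.30 and 5.48. A neighbouring intronic region (chromosome 13, 56112544 to 56112975) was called in both KO libraries and in control replicate 2, so this stretch was not without a peak in the controls.

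The first comparison asks which regions were called in 1 group only. Merging the 4 lists gave 54823 regions, of which 26744 were called in every library. A further 1862 regions were called in both KO libraries and neither control (KO-only), and 2172 in both controls and neither KO library (control-only). Most were weak: their weakest −log10 q had a median of 5.74 and 5.79, where all peaks of a library had medians of 12.2 to 12.5. Their median widths were 365 and 367 bp, against 718 bp for regions called in every library. A missing call does not show that a region was closed in the other group. Among the strongest KO-only regions was the promoter of Hs3st3b1, a heparan sulfate sulfotransferase. Among the strongest control-only regions was an intron of Nrg1, which encodes the ErbB ligand neuregulin. The 2 groups together had 4034 exclusive regions, while the same count for the 2 other ways to pair the libraries, each pair holding 1 KO and 1 control library, was 1902 and 1961. With 3 possible splits no p below 0.333 can be reached. The excess was larger among strong regions, whose peaks lay in the upper part of their lists by −log10 p in both libraries, where 44 KO-only and 65 control-only regions stood against 2 and 5 regions in the mixed splits.

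**Figure D1:**
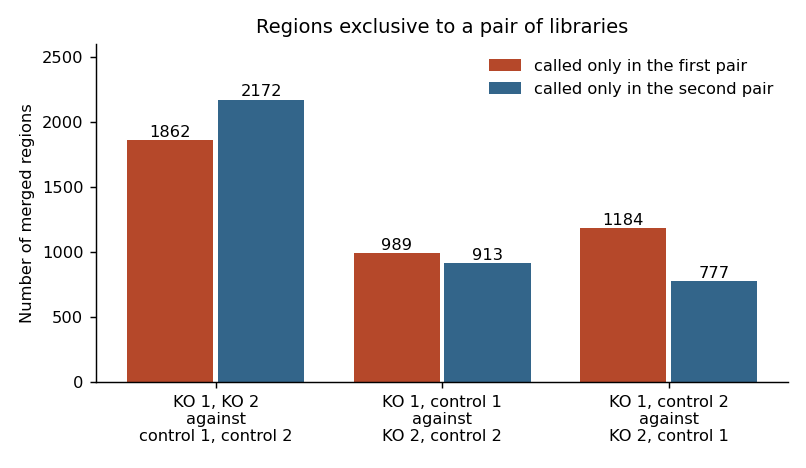
Number of merged regions called in both libraries of a pair and in neither library of the other pair, for the 3 ways to split the 4 libraries into pairs. The split by group gave 1862 and 2172 regions, and the mixed splits gave 777 to 1184 per pair.

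The 5 regions of each kind with the highest weakest −log10 q over their libraries were as follows. The Hs3st3b1 promoter region (chromosome 11, 63922136 to 63922703) had folds of 13.8 and 10.2 in KO replicates 1 and 2. An intergenic region 283931 bp from the start of Trps1, a GATA-type zinc finger repressor, lay at chromosome 15, 51173966 to 51174822, with folds of 9.45 and 9.55. An intron of Mylk, the myosin light chain kinase gene (chromosome 16, 34839441 to 34840078), had folds of 9.92 and 11.3. Sh3rf3 had an intronic region (chromosome 10, 58915686 to 58916360, folds 9.56 and 12.9), and a promoter region of Lgr6, a receptor of R-spondins, lay at chromosome 1, 135016758 to 135017328 (folds 7.20 in both). Of the control-only regions, the Nrg1 intron (chromosome 8, 32117742 to 32118490) had folds of 12.3 and 11.1 in control replicates 1 and 2. An intergenic region 298894 bp from Rnd3 lay at chromosome 2, 50849780 to 50850652 (folds 9.14 and 12.2). Tmprss5, a transmembrane serine protease gene, had a promoter region at chromosome 9, 49102403 to 49103096 (folds 12.3 and 11.8). An intergenic region near Myof, the myoferlin gene, lay at chromosome 19, 37806860 to 37807414 (folds 9.79 and 10.1), and a region assigned to Gm6133 at chromosome 18, 78380007 to 78380694 (folds 10.2 and 10.5).

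Several genes had more than 1 exclusive region, all on the same side. Myo10, an unconventional myosin of filopodia, had 4 KO-only regions among 24 regions assigned to it. Tcf4, a bHLH transcription factor, and Znrf3, a negative regulator of WNT receptors, had 3 each. Litaf, Ctsb and Filip1l also had 3 KO-only regions, and Ttc28, Scube1 and Ift81 had 2. On the control side Sh3gl3, an endophilin gene, had 4 control-only regions among 10. The collagen genes Col22a1 and Col4a1, the actin-binding protein genes Ablim1 and Palld, and Ccser1, Rcan2, Tspan9, Scfd2 and Lclat1 had 3 each. None of these genes had an exclusive region of the opposite kind. Genes with many regions have more chances to hold several, and no test per gene was made. Litaf and Filip1l lie on chromosome 16, Znrf3 on chromosome 11, and Col4a1 and Palld on chromosome 8. Exclusive regions of these chromosomes leaned to the same side as a whole, as given below. The other genes named here lie on other chromosomes.

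KO-only regions lay at promoters more often than control-only regions. Of the 1862 KO-only regions, 210 (11.3%) overlapped the 1 kb around a protein-coding transcription start, against 140 of 2172 control-only regions (6.45%). The log2 odds ratio was 0.88 (95% interval 0.56 to 1.20, Fisher's exact test, two-sided, p = 6.2e-08). In the mixed splits the same contrast gave p = 0.468 and 0.227 by Fisher's exact test. Introns held similar shares of KO-only and control-only regions (43.1% and 42.7%), as did exons (2.31% and 2.39%). The smaller promoter share of control-only regions went with a larger intergenic one, 48.4% against 43.3% of KO-only regions. Both kinds of region were far less often at promoters than the regions called in all 4 libraries, of which 41.0% were. The test counts regions called in these 4 libraries, which are not biological replicates. The log2 odds ratio was 0.34 with regions rebuilt from summit windows, 2.76 over strong regions alone, and 0.46 and 0.49 without KO replicate 1 or 2.

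The 10 KO-only promoter regions with the strongest peaks belonged to genes with no promoter peak in either control library. Besides Hs3st3b1 and Lgr6 they included Dhx58, which encodes the RNA sensor LGP2 (folds 6.97 and 8.24), Ebf3, a neuronal transcription factor gene (8.45 and 8.21), and P2ry1, a purinergic receptor gene (9.09 and 9.02). Scube1 (9.21 and 9.05), Scnn1g, a sodium channel subunit gene (9.42 and 9.49), Rtl6 (10.6 and 9.20), Sh3rf3 (9.04 and 7.91) and Pxdc1 (7.39 and 7.67) completed the set. The control-only set held Wnt11, a non-canonical WNT ligand gene (folds 9.47 and 7.94), Bscl2, which encodes seipin (7.09 and 7.05), Aes, a Groucho-type corepressor gene (7.58 and 5.34), AA467197 (8.25 and 7.62), and the zinc finger genes Zfp791 (11.3 and 9.62), Zfp105 (7.34 and 8.05) and Zfp976 (7.37 and 12.2). The other 3 control-only promoter regions, at Tmprss5, Cul4b and Cxadr, belonged to genes that had another promoter peak in both KO libraries. Counted by gene, 115 genes had a promoter peak in both KO libraries and neither control, and 55 the reverse, a total of 170 against 69 and 77 in the mixed splits.

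Chromosome 8 stood apart from the rest of the genome. It held 54 KO-only and 154 control-only regions, a log2 odds ratio of −1.34 against the other chromosomes (95% interval −1.80 to −0.89, Fisher's exact test, adjusted p = 2.4e-08). Chromosome 11 held 142 KO-only and 97 control-only regions (log2 odds ratio 0.82, 95% interval 0.44 to 1.20, Fisher's exact test, adjusted p = 0.00024), and chromosome 16 held 96 and 65 (0.81, 0.35 to 1.28, Fisher's exact test, adjusted p = 0.0033). The X chromosome, on which macroH2A1 accumulates in female cells when 1 copy is silenced, had 35 KO-only and 60 control-only regions and did not pass (log2 odds ratio −0.56, 95% interval −1.16 to 0.04, Fisher's exact test, adjusted p = 0.153). Chromosomes 10 (log2 odds ratio −0.48), 17 (−0.56) and 7 (0.48) came close, with adjusted p values of 0.0505 to 0.0579 by Fisher's exact test. Tests were two-sided and adjusted over 20 chromosomes by the Benjamini-Hochberg procedure. No chromosome passed in either mixed split, where the smallest adjusted p values by Fisher's exact test were 0.214 and 0.273. With equal lists of the 20000 strongest peaks per library, chromosome 8 passed at a log2 odds ratio of −1.20 while chromosomes 11 (0.20) and 16 (0.66) did not, and over the 109 strong regions no chromosome did, with chromosome 8 at −3.02 (Fisher's exact test, adjusted p = 0.541). Without KO replicate 1 the log2 odds ratios were −0.83 for chromosome 8 and 0.43 for chromosome 11, and without KO replicate 2 that of chromosome 11 was 0.44, all still past the threshold by Fisher's exact test.

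**Figure D2:**
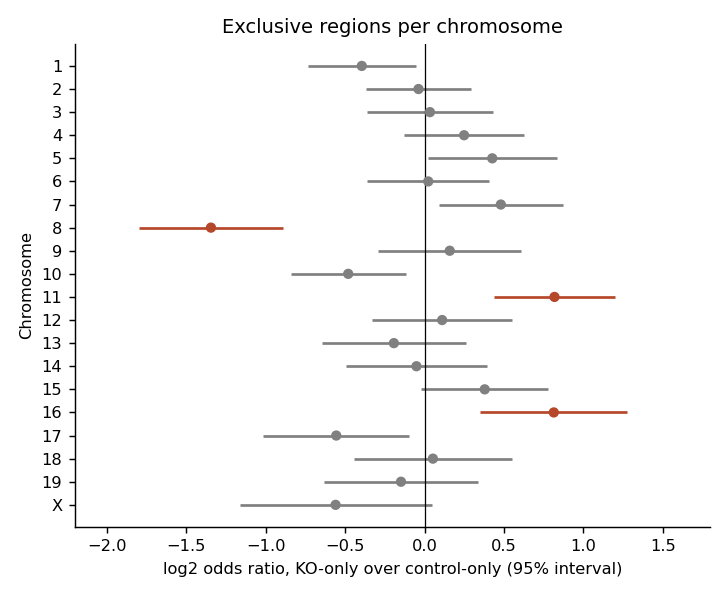
Log2 odds ratio of KO-only over control-only regions for each chromosome against the others (x axis), with 95% intervals as lines. The 3 chromosomes in red, 8, 11 and 16, passed an adjusted p of 0.05 in Fisher's exact test, and grey ones did not.

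Regions open in every library also differed by chromosome, though not always as the exclusive regions did. Over the 1322 such regions on chromosome 8 the median log2 ratio of KO to control reads at the summit was −0.16 (95% bootstrap interval −0.17 to −0.14). It was −0.12 on chromosome 17, −0.08 on chromosome 10 and 0.09 on chromosome 16. Medians of the same chromosome differed by at most 0.025 between libraries of 1 group. On chromosome 11, which passed the test of exclusive regions, the median was 0.03 (95% bootstrap interval 0.01 to 0.04). It was higher on several chromosomes that did not pass, chromosomes 9 (0.08), 12 (0.07) and 7 (0.06) among them. Where reads were instead scaled by background, the median over all regions moved by 0.15, so these values are relative to the genome-wide median. These read numbers were recovered from the authors' fold and p values, a step chosen after seeing the data.

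**Figure D3:**
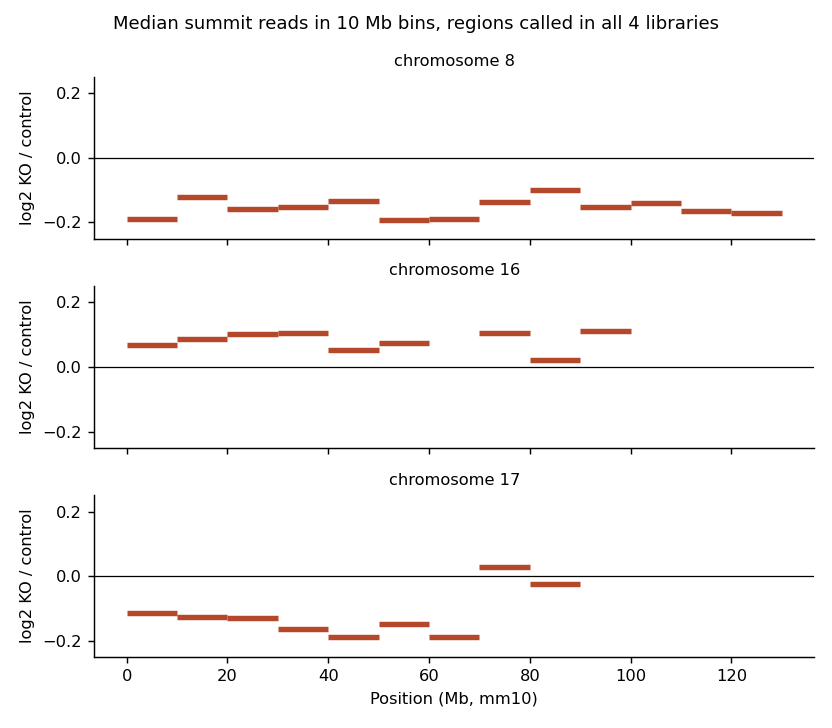
Median log2 ratio of KO to control summit reads (y axis) in bins of 10 Mb along chromosomes 8, 16 and 17 (x axis), over regions called in all 4 libraries, after each library was centred on its median. All 13 bins of chromosome 8 lay between −0.19 and −0.10, and those of chromosome 17 below 70 Mb lay lower than those above.

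The next comparison asks whether exclusive regions gathered at genes of cell state, immunity or development. None of the 20 gene lists fixed before the data were examined differed between KO-only and control-only regions after adjustment (Fisher's exact test, smallest adjusted p = 0.78). The list closest to it was that of Polycomb and DNA methylation genes, with 4 KO-only and 0 control-only regions (unadjusted p = 0.0465, Fisher's exact test, the only list under 0.05 before adjustment). Its regions were assigned to Dnmt3a (2 regions), Suz12 and Phc2, the last at the promoter. Only 92 exclusive regions fell to list genes. Most lists held too few to pass even with all of their regions on 1 side, as the Polycomb list shows. For those lists the test cannot tell whether they differed, and the larger lists could show only large differences. In simulated data the list with most regions was called in 66.0% of simulations at an odds ratio of 4 and in 100% at 8. The odds ratio there added KO-only regions to the observed share, so the simulated list held more exclusive regions than any actual list. The largest actual list held 4 KO-only and 7 control-only regions. These rates therefore overstate what the lists could show.

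Immune lists gave small counts in both directions. Interferon response and nucleic acid sensing genes had 6 KO-only and 2 control-only regions (log2 odds ratio 1.59, 95% interval −0.52 to 3.69). The KO-only ones included regions assigned to Mavs, Ifnar1, Ifnar2, Ifngr2 and Ifit1, and the control-only ones were assigned to Adar and Tlr3. The Ifit1 and Tlr3 regions lay 44199 and 43948 bp from the start of the gene. The Ifnar2, Ifnar1 and Ifngr2 regions all lie on chromosome 16 and the Tlr3 region on chromosome 8. MHC class I antigen presentation genes had 2 and 2, with a KO-only promoter region at H2-T23 (chromosome 17, 36032520 to 36032891, folds 4.96 and 6.76). The others were a control-only region assigned to B2m and 1 of each kind assigned to H2-K1. Chemokine and NF-kB genes had 3 KO-only (Nfkb1, Nfkbia, Tnfaip3) and 4 control-only regions (Cxcl1, Lif, Nfkb1, Nfkb2). Checkpoint and NK ligand genes had 2 (Nt5e, Tnfrsf10b) and 3 (Cd276, Cd47, Fas).

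No list of neuroblastoma cell state passed the test either. Adrenergic transcription factors had 0 KO-only and 2 control-only regions, assigned to Hand2 and Tfap2b. Catecholamine and sympathetic neuron genes had 1 (Elavl3) and 4 (Nefl with 2, Dlk1, Slc18a2). Mesenchymal transcription factors had 4 (Glis3, Junb, Nr3c1, Tead1) and 5 (Irf2 with 2, Prrx1, Tead1, Zfp217), and mesenchymal and matrix genes had 4 (Anxa2, Col5a1, Col6a1, Postn) and 4 (Bgn, Ccn2, Col3a1, Col5a1). The strongest of these was the intergenic region near Postn, the periostin gene (chromosome 3, 54413166 to 54413684, folds 10.3 and 10.99 in the KO libraries). The control-only Hand2 and Irf2 regions lie on chromosome 8, as does the KO-only Junb region. Axon guidance and neural adhesion genes had 6 KO-only (Efna5, Sema3c and Slit1 among them) and 2 control-only regions (Plxna2, Sema3e; log2 odds ratio 1.59, 95% interval −0.52 to 3.69). WNT, BMP and TGF-beta genes had 4 (Tcf7l2 with 2, Bmp2, Smad7) and 7, of which 2 were assigned to Wnt5b and the others to Wnt11, Lef1, Tcf7l1, Tcf7l2 and Tgfb3. Hox genes had 4 (Hoxa3, Hoxa7, Hoxd3, Hoxd10) and 2 (Hoxb9, Hoxc8). Neural crest genes had 0 and 2 (Pax3, Snai1), cell cycle genes 1 (Ccnd1) and 1 (Aurkb), and histone H2A variant genes 1 (H2afy) and 0.

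Markers of other cell types had few exclusive regions in either group. Macrophage markers had 0 KO-only and 1 control-only region (Lyz2), lymphocyte markers 1 (Ptprc) and 0, endothelial markers 1 (Esam) and 1 (Tek), and epithelial and hepatocyte markers 0 and 4 (Cdh1, Krt8, Krt18, Ttr). Housekeeping genes had 2 and 0, the former including a region at the Gapdh promoter, which was called in every library through another peak.

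The share of called promoters differed between lists in both groups. Over all 21829 protein-coding genes, 11140 had a promoter peak in every library. All 4 libraries called promoters of 28 of the 32 mesenchymal transcription factors, Runx1, Fosl1, Snai2 and Twist1 among them. Of the 22 adrenergic factors 9 were called in all 4, and 12 were called in none, including Phox2a, Hand1 and Gata2. Likewise 24 of 32 mesenchymal and matrix genes but 6 of 28 catecholamine and neuron genes had a promoter peak in every library, with Dbh, Ddc, Chga and Stmn2 in none. No promoter of lymphocyte markers was called, and those of all 15 housekeeping genes were. A promoter without a peak at this depth is not shown to be closed. Whether these shares reflect a mesenchymal or adrenergic state of the line was not tested.

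The number of called promoters differed little between groups. Over 21829 protein-coding genes it was 11719 and 11647 in the KO and 11565 and 11578 in the control libraries, so both KO libraries lay above both controls. The KO mean exceeded the control mean by 111.5 genes, with a within-group SD of 36.6. Adrenergic transcription factors had 10 and 10 called promoters in the KO libraries against 10 and 9, catecholamine and neuron genes 7 and 6 against 8 and 6, and matrix genes 26 and 26 against 24 and 26. Axon guidance genes had 17 and 18 against 15 and 16. Hox genes had 6 and 5 against 4 and 4, with Hoxa7 and Hoxd10 as the genes called only in the KO libraries. Of the MHC class I genes 17 and 19 were called against 18 and 17, with H2-T23 as the KO-only gene, and in the WNT, BMP and TGF-beta list Bmp2 was KO-only and Wnt11 control-only. Hox and axon guidance genes were the only 2 of the 20 lists in which both KO libraries lay outside both controls, a separation that chance gives 33.3% of lists when no values tie. The difference of group means for Hox genes went from 1.5 to 0.5 with the 20000 strongest peaks and to 2.5 with a start window of 2.5 kb, and with the 20000 strongest peaks that of catecholamine and neuron genes turned from −0.5 to 1, that of matrix genes went from 1 to 2.5 and that of MHC class I genes from 0.5 to 2.

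**Figure D4:**
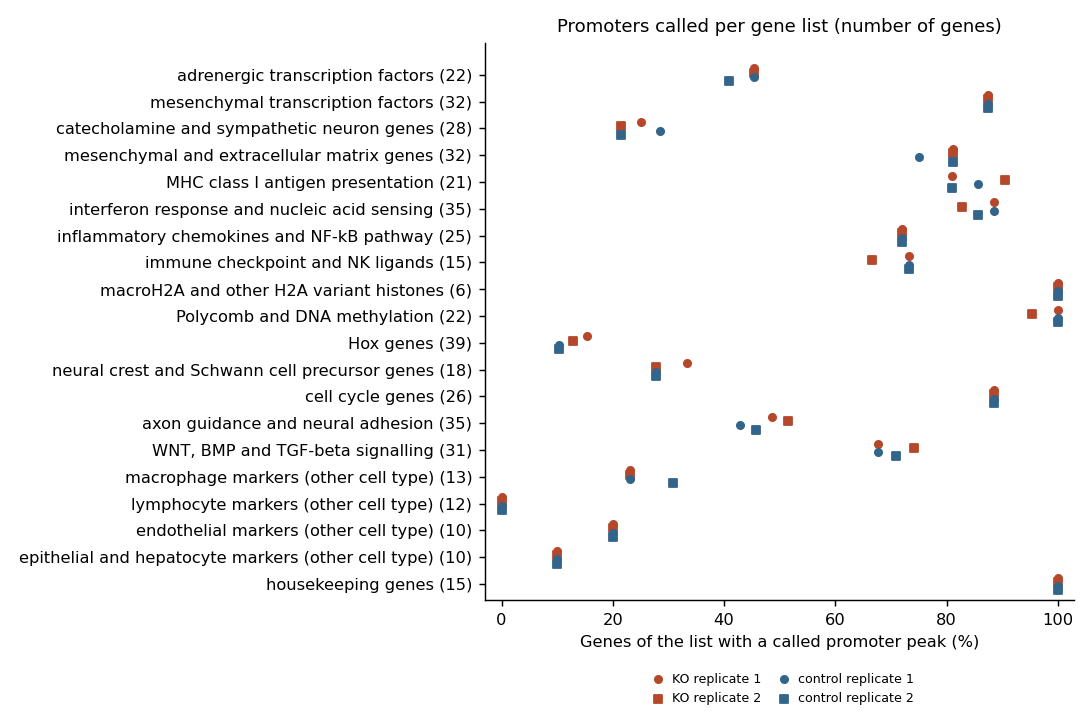
Percentage of the genes of each list (x axis, list size in parentheses) with a called peak within 1 kb of a transcription start, as 1 point per library. Mesenchymal transcription factors lie at the same value in all 4 libraries, and Hox and axon guidance genes lie higher in both KO libraries than in both controls.

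Ranked by fold within each library over the 11140 promoters called in all 4, list medians varied between replicates as well as between groups. Adrenergic factors stood at 32.0 and 49.6 in the KO libraries against 20.9 and 35.4, catecholamine and neuron genes at 70.9 and 44.8 against 50.3 and 50.2, and checkpoint genes at 40.0 and 42.6 against 38.5 and 64.1. In 4 of 17 lists both KO libraries lay outside both controls, where chance gives 5.67. Interferon genes had a median percentile of 48.5 and 48.3 in the KO libraries against 59.6 and 51.7, Polycomb and DNA methylation genes 24.1 and 27.1 against 33.9 and 29.2, housekeeping genes 19.6 and 20.0 against 26.8 and 22.1, and chemokine and NF-kB genes 36.6 and 33.0 against 32.9 and 26.7. Ranked by −log10 q, the difference between group means went from 4.98 to −7.21 percentile points for the last list, from −5.96 to −2.70 for Polycomb and DNA methylation genes and from −4.59 to −1.96 for housekeeping genes, and that of catecholamine and neuron genes turned from 7.61 to −4.84.

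The last comparison asks which transcription factor motifs separated distal regions of the 2 groups. An E-box of the HAND and TWIST type (CATCTG), bound by bHLH factors of the sympathetic and mesenchymal lineages, was present within 100 bp of the summit in 297 of 1652 distal KO-only regions (18.0%) and 518 of 2032 distal control-only regions (25.5%). The log2 odds ratio was −0.64 (95% interval −0.87 to −0.41, Fisher's exact test, adjusted p = 1.1e-06). Over all distal regions of the merged set the motif was present in 21.7%. The RUNX motif was also less frequent in KO-only regions (6.84% against 9.45%, Fisher's exact test, adjusted p = 0.0294). The motifs of CTCF, the insulator protein (7.93% against 5.51%), and TFAP2 (4.42% against 2.66%) were more frequent there, each with an adjusted p of 0.0294 by Fisher's exact test. With GC strata RUNX (log2 odds ratio −0.44) and TFAP2 (0.64) no longer passed (exact conditional test, adjusted p = 0.0858 for both) and the ISL/LHX homeobox motif did (0.48, adjusted p = 0.0401). With chromosome as a stratum, an alternative chosen after seeing the data, CTCF no longer passed (0.51, exact conditional test, adjusted p = 0.0544). Peaks of −log10 q of 5 or more also ended the RUNX (−0.36) and TFAP2 (0.56) calls, and summit windows or a motif window of 50 bp on each side ended all 3. With summit windows the log2 odds ratios changed little, at −0.45 for RUNX, 0.51 for CTCF and 0.64 for TFAP2 (Fisher's exact test, adjusted p = 0.0550 for each).

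The other 21 motifs did not pass in this test. The AP-1 motif was in 21.9% and 23.7% of distal KO-only and control-only regions and the GATA motif in 14.0% and 16.3%. The ISL/LHX homeobox motif (10.6% and 8.22%) and the CREB motif (0.242% and 0.738%) had unadjusted p values of 0.0141 and 0.0389 by Fisher's exact test. IRF, STAT and NF-kB motifs had adjusted p values between 0.578 and 1 by Fisher's exact test. Neither mixed split gave a motif under 0.05 even before adjustment, and the E-box stood there at 19.8% against 19.8% and 22.5% against 21.0%. A match to a consensus does not show binding. The E-box call ended over strong regions alone (log2 odds ratio −0.89, Fisher's exact test, adjusted p = 1), and with the 20000 strongest peaks per library it was the only motif called, RUNX standing at a log2 odds ratio of 0.31, TFAP2 at 0.00 and CTCF at 0.71. Without KO replicate 1 RUNX (−0.31), CTCF (0.18) and TFAP2 (0.30) did not pass, without KO replicate 2 CTCF (0.23) and TFAP2 (0.37) did not, and without control replicate 1 TFAP2 (0.47) did not. With 1 library left out others did pass Fisher's exact test: AP-1 without KO replicate 1 (−0.39, adjusted p = 5.1e-06) or 2 (−0.27, adjusted p = 0.00677), CREB (−1.45) and REST (3.85) without KO replicate 2 (adjusted p = 0.0381 for both), and GATA without control replicate 1 (−0.38, adjusted p = 0.000691). The E-box passed without any 1 library, with log2 odds ratios of −0.38 and −0.41 without control replicate 1 or 2.

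**Figure D5:**
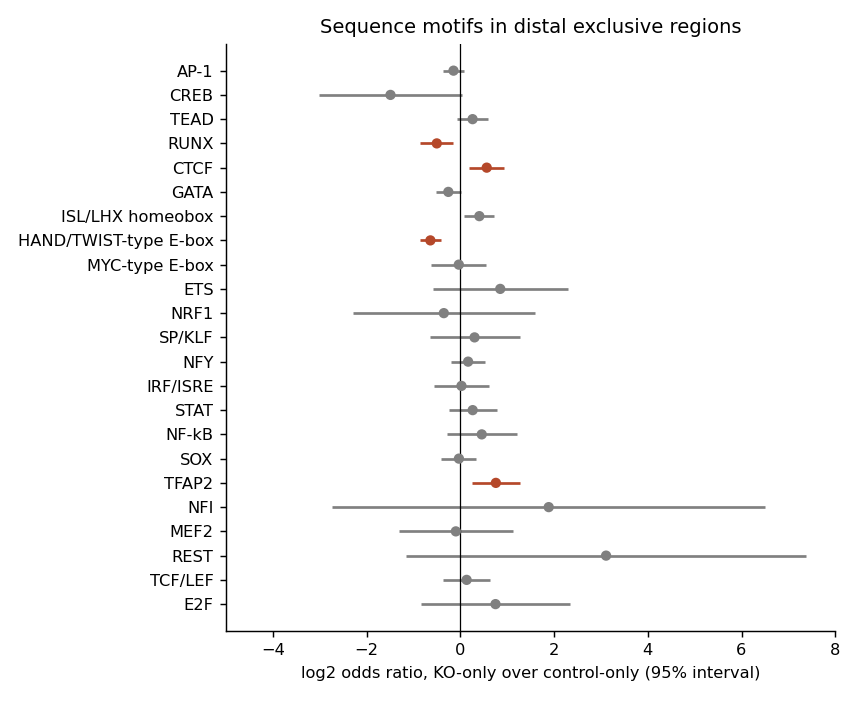
Log2 odds ratio of each plotted motif in distal KO-only over control-only regions (x axis) with 95% intervals as lines. Red marks the 4 motifs that passed an adjusted p of 0.05 in Fisher's exact test: the HAND/TWIST-type E-box and RUNX below 0, CTCF and TFAP2 above 0.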

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

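The tests on summit reads, their alternatives and the chromosome stratum for motifs were chosen only after the result was seen. Of 806 results under alternatives, 691 stayed on their side of the threshold or moved little, 27 fell below it, 12 passed it anew, 74 moved and 2 reversed. Results that passed in neither setting were counted among the 691 even where their sign turned. The housekeeping list, for instance, went from a log2 odds ratio of 2.53 to −0.52 with summit windows. The promoter share kept its direction and side under all its alternatives, at log2 odds ratios of 0.34 to 2.76. No gene list passed under any alternative. The cause of the shifts below was not tested, except that fewer peaks or fewer libraries change counts by construction. With peaks of −log10 q of 5 or more, 5 chromosomes and 2 motifs passed, against 3 and 4. With the 20000 strongest peaks per library there were 860 KO-only and 930 control-only regions, 2.35 times the larger mixed split against 2.06, and 1 chromosome and 1 motif passed, while RUNX reversed to 0.31. Summit windows gave 1.84 times the larger mixed split and 1 motif. Strong regions gave 44 and 65 regions, 21.8 times the larger mixed split, 0 chromosomes and 0 motifs by Fisher's exact test, with the E-box at −0.89 and RUNX reversed to 0.049. A motif window of 50 bp on each side left 1 motif. Without 1 library each, KO-only regions numbered 3234 to 5427 and control-only regions 3606 to 6130, 4 to 7 chromosomes and 2 to 5 motifs passed. The replicate block, over regions called in 1 library of a same-numbered pair, gave 10 motifs, a promoter log2 odds ratio of 0.48, an E-box one of −0.33 and 855 limma calls. Deviations of same-numbered libraries had a correlation of 0.0103 over regions. These deviations are close to counting error alone, so this value cannot tell whether same-numbered libraries shared a batch. At about 21 reads per median summit, small differences between libraries lie within counting error.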

Other observations

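The limma test of summit reads, the test of E-box regions called in all 4 libraries, the test of promoter against distal reads, the chromosome stratum for motifs and the word search were chosen only after the result was seen. Among 26742 regions open in all 4 libraries, limma called 851 at an adjusted p under the threshold, 298 higher and 553 lower in the KO libraries. The promoter of Pard3b, a polarity gene, had 41 and 40 reads at the summit in the KO libraries against 13 and 10 in the controls (log2 difference 1.83, SE 0.28, limma adjusted p = 5.9e-08). Nectin3, an adhesion receptor gene, had 76 and 74 against 36 and 27 (1.30, SE 0.17, limma adjusted p = 6.5e-11), and the promoters of Thrb (1.43), Sybu (1.34), Alcam (1.28) and Cadps (1.27) were also higher. Libraries of 1 group differed by little more than counting noise, and the labels do not say that they were separate cultures. The SEs and p values of this and the next paragraph may therefore not cover the spread between cultures. The counts of calls rest on the variance model and the scaling. Without both the variance trend and the robust moderation limma called 0 regions (3748 at an unadjusted p under 0.05, against 4120 with both), scaling by background gave 901 higher and 288 lower, and leaving out 1 library gave 479 and 481 calls without KO replicate 1 or 2, and 277 and 279 without control replicate 1 or 2. Mixed splits gave 0 limma calls each, with 489 and 468 at an unadjusted p under 0.05. These fits held no term for group, so the difference of KO and control counted as residual spread and made calls less likely. They therefore do not measure how many of the 851 calls are false.

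Among promoters with fewer KO reads, that of Pecam1, an endothelial and leukocyte adhesion gene, had 41 and 44 against 105 and 112 reads (log2 difference −1.30, SE 0.13, limma adjusted p = 8.5e-18), and an intron of the same gene was lower too (−1.48). The promoter of Gng2, a G protein subunit gene, had 14 and 11 against 42 and 43 (−1.69), and that shared by Bco2 and Il18 stood at −1.22. The largest drops were distal. A region in an intron of Dtna (chromosome 18, 23529026 to 23529724) had 6 and 8 reads against 43 and 46 (−2.55, SE 0.30, limma adjusted p = 1.7e-13), and regions assigned to Wnt16 (−1.98), Adarb2 (−1.97), Rbpj (−1.69) and Nrg1 (−1.65) followed. The direction of called list members passed for no fixed list (Fisher's exact test, adjusted p = 1 for each), and called members went both ways. The lists held too few called regions for any to pass. Even the endothelial list, with 0 higher and 3 lower, had an unadjusted p of 0.289 by Fisher's exact test. The comparison therefore cannot tell whether a list differed in direction. The promoter of Th, the rate-limiting enzyme of catecholamine synthesis, was higher (0.56, limma adjusted p = 0.0128) and so was a region near Hand2 (1.18), while regions of Gata3 (−1.31), Runx2 (−1.08), Klf7 (−0.89), Csf1 (−0.90) and the Ccl2 promoter (−0.55) were lower. Called regions of other-cell-type markers were all lower, with 3 of 14 endothelial regions (2 at Pecam1, and 1 near Kdr at −0.90; list median −0.29) and 1 of 6 epithelial ones (Cdh1, −0.93). Of the called promoters 86 were higher and 55 lower, and of the called distal regions 212 and 498.

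Chromosome 8 had fewer KO-only than control-only regions, and its regions open in all libraries also had fewer KO reads. The log2 odds ratio was −1.20 (95% interval −1.81 to −0.58) with lists of equal length. Cutting the lists does not equalise the depth of the libraries, so deeper controls are not excluded by it. The 2 controls differed more in background (0.858 and 0.967 reads) than KO and control replicate 1 (0.806 and 0.858). Over regions open in all libraries, the chromosome 8 median of control replicate 1 minus 2 was −0.004. For KO replicate 1 minus control replicate 1 it was −0.15. For these regions the values argue against depth as the cause. The shift was not limited to distal regulation, since promoters on chromosome 8 were shifted by −0.17 (95% bootstrap interval −0.20 to −0.15) against promoters elsewhere, and distal regions by −0.16. A copy number difference in part of the cells would lower the whole chromosome, and 100% of its 13 bins of 10 Mb lay below 0, so such a difference between the cultures may underlie the pattern. A chromosome-wide effect of the lost histone would look alike and stays open, and chromosome 10 had all 13 bins below 0 and chromosome 16 none of 9.

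The HAND/TWIST-type E-box was less frequent in distal KO-only than control-only regions. GC content does not account for it (log2 odds ratio −0.62 with GC strata), nor do chromosome-wide shifts (−0.63 with chromosome as a stratum). With lists of equal length the log2 odds ratio was −0.70 (95% interval −1.05 to −0.36). The depth of the libraries stays unequal in such lists, so deeper controls are not excluded. Distal regions called in all 4 libraries and holding the motif differed from those without it by −0.060 in the median log2 ratio of KO to control reads (95% bootstrap interval −0.08 to −0.04), against 0.01 and 0.00 between libraries of 1 group. Lower accessibility at sites of bHLH factors in the KO cells is therefore a candidate explanation, small in size and found on the same data. Which factor binds, and whether the cultures differed in state for another reason, was not tested.

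Promoters made up more of the KO-only than of the control-only regions. The log2 odds ratio was 0.83 (95% interval 0.45 to 1.21) with lists of equal length. Such lists still come from libraries of unequal depth, so deeper controls are not excluded. In regions open in all 4 libraries, the median log2 ratio of KO to control was higher by 0.037 at promoters than at distal regions (95% bootstrap interval 0.03 to 0.04), so slightly stronger promoter enrichment in the KO libraries as a whole may contribute. The 2 controls themselves differed by 0.014 in the same measure (95% bootstrap interval 0.004 to 0.021), without any difference of group. A gain at promoters caused by the knockout itself stays open and was not tested.

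Among all 2080 words of 6 bases, the reverse complement of that E-box, CAGATG, had the smallest p (adjusted p = 9.0e-05, Fisher's exact test), and 34 words passed the threshold, 14 of them more frequent in control-only regions. The next was ATTCAC, in 6.11% of distal KO-only and 10.8% of control-only regions. Chromosome 17 had medians of −0.19 to −0.12 in its bins below 70 Mb, and 0.03 and −0.02 in the 2 above.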
